A study of Homo sapiens with 10 samples.

How the data were processed

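Total RNA from SK-N-FI and SK-N-AS cells was extracted with Trizol, labelled with biotin by a whole-transcript sense target protocol and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are log2 signals per probe set. The submitters' processing notes name RMA and Transcriptome Analysis Console 4.0.1.36, without saying which step each was used for. RMA corrects background, normalizes arrays by quantiles and summarises probes, so that a change shared by most genes of an array would be removed. Array medians lay between 7.02 and 7.07 in SK-N-FI and between 6.02 and 6.09 in SK-N-AS, and the lines appear to have been normalized separately. Levels set across lines therefore carry that difference. The scanner files and other settings of RMA were not used here.

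The table held 24351 probe sets on 10 arrays, of which 2903 were controls and 21448 were tested. A gene symbol was given by the platform annotation for 17709 probe sets, all with 1 symbol, and 3739 were unnamed here. Their gene identifiers were looked up in RefSeq of GRCh38.p14, where all 17709 matched. A probe set was counted as above background on an array when it exceeded the 95th percentile of 612 negative control probe sets of that array. For symbols with over 1 probe set (20 symbols), the brightest was used in gene list tests. No arrays held identical values. The depth of an array has no count, and precision rests on the number of arrays.

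Arrays were grouped by line and treatment from their titles and group labels. The series design mentions more SK-N-FI replicates than the 2 per condition analysed here. Treated and control arrays were compared within each line with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with no covariate, and a fit of all 10 arrays in 4 groups gave the difference of the effects between lines and the comparison of the control groups. P-values were adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05. A set of 41 gene lists was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Designs, lists, alternatives and the rule for named genes were fixed before the data were examined.

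Named genes were the 10 largest rises and 10 largest falls per line among genes with non-overlapping arrays that passed the threshold. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p were named and said not to pass. Of each list described, 2 to 4 members with the smallest p were named, and the 3 genes of the conjugate's targets always were. Members of lists named in the comparison of the control groups were chosen after their values were seen, as were the genes named only in the closing section.

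The fits were tested on simulated data drawn from the real means and spread, with 200 of 21448 probe sets changed. For SK-N-FI, 0% of log2 changes of 1 were recovered, 91.5% of changes of 2 and 98.5% of changes of 3. For SK-N-AS, the shares were 0%, 88.5% and 98%. Known changes were also added to the real arrays, in 10 draws per size. The probe sets were drawn at random, whether or not they exceeded the negative controls, so recovery there concerns the signal. Alternatives covered eBayes settings, quantile and median scaling, leaving out dim probe sets, array weights, other thresholds, a shared fit, a block on the array number in SK-N-FI and leaving out each array in turn. Further alternatives, chosen after seeing the data, were a residual principal component as a covariate, leaving out SK-N-AS arrays 25 and 28, a crossed block in SK-N-FI, and quantile scaling, a 2-fold threshold and left-out arrays in the comparison of the lines.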

Results

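Gene expression was measured on 10 whole-transcript arrays of SK-N-FI and SK-N-AS, human neuroblastoma cell lines, after exposure to BG-P1600-TAT or to its buffer control. BG-P1600-TAT is a polymer conjugate named in the series title as directed at the norepinephrine transporter and at the integrin αvβ3. Cells received 30 µM for 48 h, and control cells received PBS. SK-N-FI had 2 control and 2 treated arrays, and SK-N-AS had 3 control arrays (numbered 25, 26 and 27) and 3 treated arrays (28, 29 and 30). The SK-N-AS sample titles give the compound as BG-P-TAT, which was taken here to be the BG-P1600-TAT of the treatment protocol. The SK-N-AS values and the comparison of the lines rest on that reading. The small number of arrays limits the precision of every value. The labels do not say that the SK-N-AS arrays came from separate cultures, so p-values there measure the spread between arrays, which may be technical. Between 38.3% and 44.3% of 21448 gene probe sets lay above the 95th percentile of the negative control probe sets in SK-N-FI, and between 32.9% and 39.7% did so in SK-N-AS.

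The first question was which transcripts responded to the conjugate in SK-N-FI. No gene was called. The probe sets with the smallest p-values included lower values in treated cells for TAS2R14, a bitter taste receptor (log2 change -1.32, 95% interval -1.90 to -0.75), SYTL4, a granule-docking protein (-1.20, -1.72 to -0.68), SLA, an adaptor of antigen receptor signalling (-1.10), ITGA2B, the platelet integrin subunit alpha IIb (-1.10), and the keratin-associated gene KRTAP19-4 (-0.98). Higher values in treated cells were found for the olfactory receptor gene OR52N4 (1.19), NRIP3 (1.08), ARMC3 (1.00), MAML1, a Notch coactivator (0.97), and KRTAP12-2 (0.98). None of these 10 genes passed the test (limma adjusted p = 1 for each, n = 2 per group). ARMC3 exceeded the negative control threshold on 1 of 4 arrays and the other 9 on none.

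In SK-N-FI, limma called 0 of 21448 probe sets, and 611 had an unadjusted p under 0.05, where 1072.4 were expected by chance. That number was 977 without control array 2 and 1107 without treated array 1. Treated and control arrays did not overlap for 27.8% of probe sets, against 33.3% by chance. The 95% interval of the change excluded a 2-fold difference in either direction for 84.9% of probe sets and a 4-fold difference for 99.9%. Only 8171 of the 21448 exceeded the negative control threshold on every SK-N-FI array. For the others the interval describes a signal at or near background and says little about the transcript. When known changes were added to 200 probe sets of the real SK-N-FI arrays, the fit over 21448 probe sets recovered 0% of 2-fold changes, 89.95% of 4-fold changes and 99.5% of 8-fold changes. These shares hold for 200 probe sets changed at once. With fewer changed, the adjusted threshold is harder to reach, and recovery of a change in a few genes was not tested.

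The same question was asked in SK-N-AS. No single gene was called here either. TSHZ2, a zinc finger homeobox gene, had a log2 change of 1.09 (95% interval 0.58 to 1.596), and SGO2, a protector of centromeric cohesion, of 1.47 (0.54 to 2.39). SORBS3, a vinculin-binding adaptor, had a change of 0.78, SOHLH2 of 0.77 and ANKRD26 of 0.76. Lower values in treated cells were found for NME6 (-1.08, -1.63 to -0.52), DRC2, a component of ciliary dynein regulation (-1.05), LCE6A (-0.95), GRTP1 (-0.89) and RGS7BP (-0.85). None of these 10 genes passed the test (limma adjusted p = 1.00 for each, n = 3 per group). SOHLH2 exceeded the negative control threshold on 1 of 6 arrays and the other 9 on none.

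In SK-N-AS, limma called 0 of 21448 probe sets, and 557 had an unadjusted p under 0.05, against 1072.4 expected by chance and 1123 with array weights. The plain equal-variance test with Benjamini-Hochberg adjustment also called 0. Treated and control arrays did not overlap for 7.31% of probe sets, where chance gives 10%. The 95% interval excluded a 2-fold difference for 82.1% of probe sets and a 4-fold difference for 99.3%. Here 6621 of the 21448 exceeded the negative control threshold on every SK-N-AS array, and the same limit holds for the others. Known changes added to 200 probe sets of the real SK-N-AS arrays, over 21448 probe sets, were recovered at 0% for 2-fold, 89.2% for 4-fold and 98.2% for 8-fold changes. Recovery of a change in only a few genes was not tested here either, and would be lower. The largest source of variation among the 6 arrays lay within the arms. The first principal component held 50.04% of the variance, with scores of -57.5, 26.9 and 4.33 for control arrays 25, 26 and 27 and of -31.0, 6.71 and 50.6 for treated arrays 28, 29 and 30.

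The NF-kB and inflammatory list holds NF-kB subunits, their inhibitors and target cytokines. In SK-N-AS, 20 of its 23 members had a lower mean in treated than in control cells and 3 a higher one, and the median log2 change was -0.35. LIF, an interleukin-6 family cytokine, went from 10.21 ± 0.27 to 9.60 ± 0.19 (log2 signal, SD, n = 3). NFKB1, the p105 and p50 subunit, went from 11.83 ± 0.13 to 11.27 ± 0.27, and RELB, a subunit of the noncanonical pathway, from 8.23 ± 0.22 to 7.73 ± 0.20. IL1A had a log2 change of 0.58 and lay below the negative control threshold on every array. No member passed the test alone, either among all genes or adjusted over the list alone.

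As a group the NF-kB list was called lower in treated SK-N-AS cells by camera with a preset correlation (adjusted p = 1.99e-05). The call was lost at adjusted p = 0.248 with an estimated correlation. The preset correlation also called up to 9 lists when the same 6 arrays were split in other ways, against 3 in the real split. The NF-kB list itself was not among the lists called in the other splits (smallest camera adjusted p = 0.115). Each of those splits mixes treated and control arrays, which by itself shrinks a difference between the arms. The missing calls there therefore add no separate support. The estimated correlation was 0.00437, under the preset 0.01, and its p-value was taken with 4 residual degrees of freedom. fry, which asks whether the members move one way without comparing them with other genes, gave an adjusted p of 0.0305. The list's mean deviation per array was 0.11, 0.14 and 0.17 in control arrays 25, 26 and 27 and -0.11, -0.15 and -0.16 in treated arrays 28, 29 and 30. An exact two-sided permutation test of these array means gave p = 0.1, the smallest value that 3 arrays against 3 allow.

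**Figure D1:**
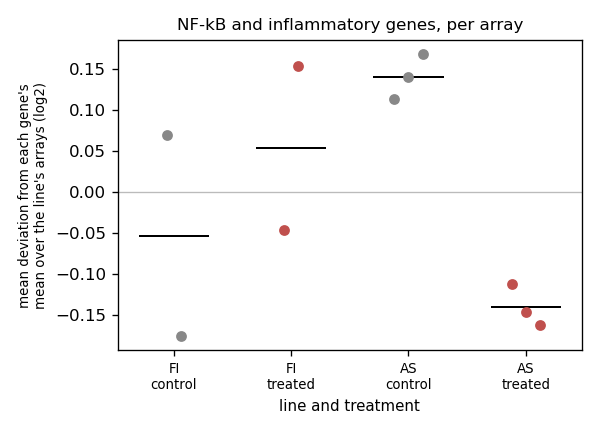
Mean deviation (log2) of 23 NF-kB and inflammatory genes from each gene's mean over the arrays of its line, on the vertical axis, for control and treated arrays of SK-N-FI (FI) and SK-N-AS (AS). Each point is an array and each bar a group mean; the 3 treated SK-N-AS arrays lie at -0.11 to -0.16 and the 3 controls at 0.11 to 0.17, while the SK-N-FI groups overlap.

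Camera with the preset correlation also called replication-dependent histones and metallothioneins lower in treated SK-N-AS cells. For the histones, 23 of 25 members were lower, with a median log2 change of -0.26 (adjusted p = 0.00102), and the call was lost at adjusted p = 0.877 with an estimated correlation. H2BC14 had a log2 change of -0.96 and H4C3 of -0.71, and neither passed the test. The histone scores also differed within the arms, at 0.49, 0.17 and -0.25 in control arrays 25, 26 and 27 and at 0.22, -0.24 and -0.39 in treated arrays 28, 29 and 30. The histone call ended without control array 25 (adjusted p = 0.460) and without treated array 30 (0.275), where the list's mean log2 change went from -0.27 to -0.09 and -0.14. The mean was -0.46 without control array 27 and -0.45 without treated array 28. For the metallothioneins, zinc- and copper-binding proteins, all 9 members were lower, with a median of -0.31 (adjusted p = 0.00363), and the call was lost at adjusted p = 0.811 with an estimated correlation. MT1E had a log2 change of -0.38 and MT1X of -0.45, and neither passed. The metallothionein scores were 0.14, 0.08 and 0.22 in control arrays 25, 26 and 27. They were 0.14, -0.25 and -0.33 in treated arrays 28, 29 and 30, so that treated array 28 lay among the controls. The metallothionein call ended without control array 27 (adjusted p = 0.0606), treated array 29 (0.0756) or treated array 30 (0.227). With fry, neither list passed (adjusted p = 0.945 for histones and 0.883 for metallothioneins).

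The other 38 lists were not called in SK-N-AS, and 0 of 41 lists were called in SK-N-FI by camera with either correlation or by fry. Of 891 distinct list genes tested in each line, 0 were called over all genes, and no list member was called when adjusted over its list alone. In SK-N-AS, 14 of 19 heat shock genes had higher means in treated cells (median 0.15, adjusted p = 0.112), among them HSPA1L at 0.58 and HSPA1A at 0.44. Control array 25 was the outlying array, as the heat shock scores were -0.38, 0.04 and 0.04 in control arrays 25, 26 and 27. In treated arrays 28, 29 and 30 they were -0.02, 0.09 and 0.23. The p53 target list had 19 of 27 members with lower means (median -0.13, adjusted p = 0.177), with TP53INP1 at -0.84 and TNFRSF10A at -0.46. For genes of integrin subunits and focal adhesion, the SK-N-AS median was -0.04 (adjusted p = 0.591), with PXN, encoding paxillin, at -0.62 and BCAR1 at -0.57. In SK-N-FI, 19 of 29 angiogenesis genes had higher means in treated cells (median 0.08, adjusted p = 0.939), among them DLL4 at 0.71 and VEGFC at 0.63.

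The genes of the conjugate's named targets were examined in both lines. SLC6A2, which encodes the norepinephrine transporter, was bright in SK-N-FI at 13.98 ± 0.61 in controls and 13.72 ± 0.21 in treated cells (log2 signal, SD, n = 2). Its change of -0.26 had a 95% interval of -0.999 to 0.47, and its sign rested on single arrays, at 0.17 without control array 1 and -0.69 without control array 2. In SK-N-AS it did not exceed the negative control threshold on any of 6 arrays. ITGAV, the integrin subunit alpha V, was above that threshold on every array, with a change of 0.28 (-0.26 to 0.82; 0.46 without treated array 1 and 0.10 without treated array 2) in SK-N-FI and 0.30 (-1.24 to 1.83) in SK-N-AS. ITGB3, the subunit beta 3, was not above the threshold on any array of either line. None of these changes passed the test (limma adjusted p = 1 in SK-N-FI and 1.00 in SK-N-AS). In SK-N-AS, ITGAV varied within the arms, at 8.04, 10.11 and 9.61 in control arrays 25, 26 and 27 and at 8.46, 9.22 and 10.98 in treated arrays 28, 29 and 30. Its change turned to -0.31 without control array 25 and to -0.42 without treated array 30.

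**Figure D2:**
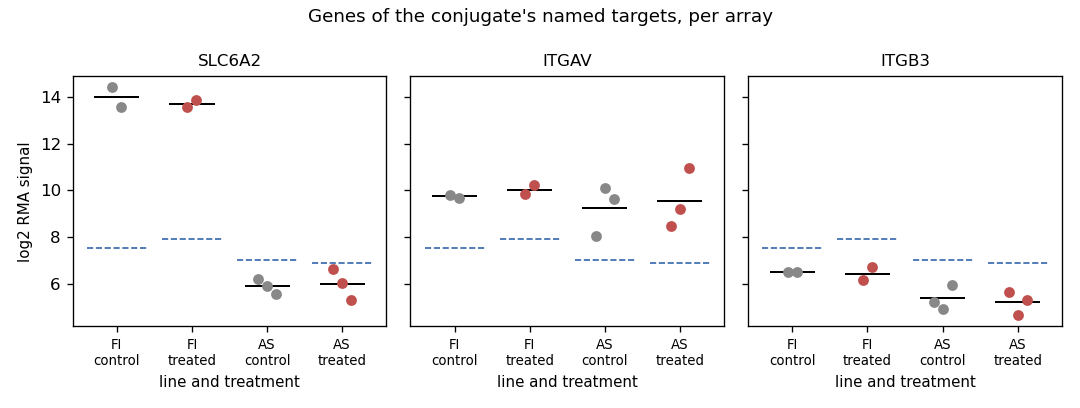
Log2 RMA signal of SLC6A2, ITGAV and ITGB3 on the vertical axis for control and treated arrays of SK-N-FI (FI) and SK-N-AS (AS). Points are arrays, black bars group means and dashed lines the group mean of the negative controls' 95th percentile; SLC6A2 lies at 13.55 to 14.41 in SK-N-FI and below the dashed lines in SK-N-AS, and the lines appear to have been normalized separately.

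The treatment effects of the lines were then compared. No probe set was called for a difference in its effect between the lines (limma interaction, 0 of 21448 called). At an unadjusted p under 0.05 there were 457, or 936 with array weights. Recovery of known changes was not tested for this difference, so smaller differences may have been missed. Across genes, which are not independent replicates, the log2 changes of both lines had a Pearson r of 0.00748 and a Spearman rho of 0.00946, and 50.5% had the same sign. Among gene lists, the NF-kB list differed between the lines, with a mean log2 change in SK-N-AS minus that in SK-N-FI of -0.39 (camera adjusted p = 5.38e-05). It did not pass with an estimated correlation (adjusted p = 0.384). The median change of this list was 0.18 in SK-N-FI, where 2 of 23 members exceeded the negative control threshold on all 4 arrays, against 16 of 23 on all 6 arrays in SK-N-AS. The histone list also differed (difference -0.30, adjusted p = 0.0142), and not with an estimated correlation (adjusted p = 0.964).

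Control arrays of the lines were compared as a check of the line labels. Genes of the noradrenergic state of neuroblastoma, which resembles sympathetic neurons, were mostly higher in SK-N-FI. Of 29 noradrenergic genes, 27 were higher in SK-N-FI. DBH, which makes noradrenaline from dopamine, had a log2 signal of 14.14 ± 0.14 (SD, n = 2) in SK-N-FI, PHOX2A, a transcription factor of sympathetic neurons, 12.54 ± 0.47, and GAP43, a growth cone protein, 14.09 ± 0.69. None of these exceeded the negative controls in SK-N-AS, so that SK-N-FI was at least 141-fold higher for DBH, at least 46.3-fold for PHOX2A and at least 126-fold for SLC6A2. Each bound sets the SK-N-FI mean against the higher of the negative control threshold and the gene's own signal in SK-N-AS. The mesenchymal list had 12 of 29 members higher in SK-N-AS and 10 higher in SK-N-FI. FN1, encoding fibronectin, and FOSL1 were higher in SK-N-AS, and CD44 was higher in SK-N-FI (log2 difference -2.70, and -0.99 after quantile normalization over all arrays).

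Limma called 12726 probe sets between the control arrays of the lines, 2473 higher in SK-N-AS and 10253 higher in SK-N-FI. Any difference of run between the lines cannot be told apart from the line itself, and quantile normalization need not remove it. The log2 differences of the probe sets, SK-N-AS minus SK-N-FI, had a median of -0.61, and this offset moves the split. After quantile normalization over all 10 arrays, 9999 were called, 5172 higher in SK-N-AS and 4827 higher in SK-N-FI. The bounds were then 63.5-fold for DBH, 17.1-fold for PHOX2A and 56.5-fold for SLC6A2, 23 noradrenergic genes were higher in SK-N-FI and 2 in SK-N-AS, and the mesenchymal list had 16 members higher in SK-N-AS and 5 higher in SK-N-FI.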

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

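Of the tests in this part, those of gene span, of treatment as the source of the array component, of dim probe sets and of the component of all 6 arrays were chosen after the results they bear on had been seen.

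The NF-kB list differed between the lines in its mean log2 change by -0.388 (SK-N-AS minus SK-N-FI), in a test of the difference itself with a preset correlation. The histone list differed by -0.301 in the same test, and neither passed with an estimated correlation.

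The lower NF-kB list in treated SK-N-AS cells was weighed against technical explanations. A shift of all bright probe sets was argued against by random lists matched on signal, of which 0% of 10000 had a mean as low as -0.28, and noise of dim probe sets by the 16 members above the negative controls on all 6 arrays, whose mean change was -0.40. The mean was -0.280 with the first principal component of all 6 arrays as a covariate, and -0.31 without arrays 25 and 28. The covariate decides little, since 93.96% of that component's variance lay within the arms and it could hardly move the estimate. That component is argued against by the list's scores, whose SD was 0.028 among control and 0.026 among treated arrays. Over the same arrays the component ranged from -57.5 to 26.9 and from -31.0 to 50.6. An earlier test with the residual component gave -0.281, the value without it, and decides nothing, since that component is centred within the arms and cannot move the estimate. Chance stays open: 1 of the 10 splits of the 6 arrays, the real one, had a mean difference as large (0.281, against 0.131 for the highest other). The 10 splits are too few for a share under 0.05. Array order and culture were not tested and also stay open. All control arrays were numbered before the treated arrays, so any effect of that order cannot be told apart from treatment. The labels do not say that the arrays of an arm came from separate cultures. The small SDs within the arms may therefore be technical, and do not argue against a difference between cultures.

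For the counts in SK-N-AS, 10 splits are likewise too few for a share under 0.05. The real split called 0 probe sets and the highest other 0, so that 10 of 10 splits had as many. The real split called 3 gene lists with the preset correlation and the highest other called 9, and 8 of 10 splits had as many. That highest split, arrays 25, 27 and 28 against the rest, also had 3133 probe sets at an unadjusted p under 0.05 against 557 in the real one, which points to a structure of the samples other than treatment. With an estimated correlation, 0 lists were called in each of the 10 splits.

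The leading component of the SK-N-AS arrays, with 50.04% of the variance, was tested against 3 sources. Treatment is argued against as its main source, since 93.96% of the component's variance lay within the arms. Overall brightness stays open, since RMA already equalises the arrays' distributions and the share of 49.7% after a further quantile normalization decides nothing. Its loadings followed gene span (Spearman rho 0.25 across 17709 genes, and 0.39 across the 5808 above the negative controls on all 6 arrays). Removing each array's trend with span left 51.0% of 52.6%, so that span is not the whole source. RNA quality and culture differences were not tested and stay open.

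Both lines had fewer small p-values than chance gives in the fits without weights or covariates, but not with array weights in SK-N-AS (1123, against 1072.4 by chance) or without treated array 1 in SK-N-FI (1107). Splits of the SK-N-AS arrays that mix the arms also gave low shares, as 2.66% for arrays 25, 29 and 30 against the rest. The split of arrays 25, 26 and 30 gave 2.70%, while the highest split gave 14.6%. A low share is thus not particular to the treatment grouping. In SK-N-AS the share at an unadjusted p under 0.05 went from 2.60% to 6.74% with the first residual component as a covariate, consistent with a component shared by both arms that widens the spread. Simulated arrays without such a component had 5.03% without and 5.08% with the covariate in SK-N-AS, and 4.98% and 5.29% in SK-N-FI. Genes were drawn independently there, so that these shares hold for uncorrelated genes only. In the real SK-N-AS arrays the covariate also raised the share in every other split, as from 2.21% to 4.57% for arrays 25, 27 and 30 against the rest. The rise is thus not particular to the treatment grouping. In SK-N-FI the share went from 2.85% to 4.40%, between the bounds set beforehand, and the explanation cannot be decided there. The empirical Bayes prior is argued against as the whole cause in both lines. A plain equal-variance test, which has no prior, gave 3.38% in SK-N-AS and 3.75% in SK-N-FI, still fewer than chance gives. These shares are above the 2.60% and 2.85% with the prior, so that a contribution of the prior is not excluded.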

How the results depend on the processing

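Counts of called probe sets stayed at 0 in both lines, for the target genes and for the difference between lines under every alternative with an adjusted p. With an unadjusted p under 0.05 and at least a 2-fold change, 24 were counted in SK-N-FI, 15 in SK-N-AS and 158 for the difference, because the threshold is not adjusted. A block on the replicate number in SK-N-FI called 0 probe sets and 0 lists. The deviations of same-numbered arrays had only a weak, negative correlation (r = -0.171), and the crossed block, chosen after seeing the data, also called 0. The residual component and leaving out arrays 25 and 28, both chosen after seeing the data, called 0 probe sets and, with the preset correlation, 4 lists each in SK-N-AS. With an estimated correlation both called 0 lists (smallest adjusted p = 0.788 and 0.651, for the NF-kB list).

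The 3 lists called in SK-N-AS became 0 with an estimated correlation and 1 with fry. Leaving out 1 array gave 1 to 7, with 7 without treated array 28 and 1 without treated array 30, and the cause was not tested. The NF-kB list was called in each of these left-out fits, with mean changes of -0.27 to -0.30. In SK-N-FI, leaving out 1 array gave 0 to 1 lists, with 1 without control array 1, and the cause was not tested. The correlation of the effects between lines was 0.0250 among the brighter probe sets and -0.0207 to 0.0289 when 1 array was left out, and the cause was not tested. The comparison of the control groups called 7495 probe sets after quantile normalization with a 2-fold threshold, both chosen after seeing the data. Quantile normalization alone gave 9999 and the threshold alone 9962, against 12726, so that both lowered the count. Of 423 values of named genes under alternatives, 10 had another sign, none of them called. All 10 were values of SLC6A2, ITGAV or ITGB3, so that the directions of these target genes are not settled. Signal over background limits the single genes: 18 of the 20 named for their p-values were not above the negative controls on any array of their line.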

Other observations

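The following genes and lists were chosen after their values were seen. Here too, line and any difference of run cannot be told apart. SK-N-AS control cells had high levels of inflammatory genes compared with SK-N-FI. Of 23 NF-kB and inflammatory genes, 18 were higher in SK-N-AS and 1 in SK-N-FI, and 19 and 1 after quantile normalization over all arrays. IL1B, the interleukin-1 beta gene, had a log2 signal in SK-N-AS controls of 17.04 ± 0.17 (SD, n = 3), and CCL2, a monocyte chemokine, of 16.83 ± 0.20. Neither exceeded the negative controls in SK-N-FI controls, so that SK-N-AS was at least 735-fold higher for IL1B and at least 635-fold for CCL2. The bounds were 75.9-fold for CCL20 and 39.5-fold for CXCL8. After quantile normalization over all arrays they were 1027-fold for IL1B, 917-fold for CCL2, 152-fold for CCL20 and 85.1-fold for CXCL8. Of the haematopoietic markers, CD14, LYZ, SPI1 and CSF1R were not above the negative controls on any SK-N-AS control array, while CD68 was above them on all 3, PTPRC, the pan-leukocyte marker, and HBA1 on 2 each, and TYROBP on 1.

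Other lists also separated the control groups. All 40 mitosis genes were higher in SK-N-FI, and 36 after quantile normalization. Genes of the integrated stress response, targets of ATF4, were higher in SK-N-AS for 18 of 32 and higher in SK-N-FI for 5, and after quantile normalization for 25 and 2. DLK1, a Notch family ligand, was at least 931-fold higher in SK-N-FI, and MYCN at least 8.87-fold. After quantile normalization over all arrays these bounds were 864-fold and 2.88-fold.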
